A study of Xenopus laevis with 4 samples.

How the data were processed

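Expression was measured with Affymetrix arrays on total RNA of Xenopus laevis whole embryonic skins, 20 per sample, from embryos kept at 15 °C. The deposited values are on the log2 scale, 1 per probe set and array. The submitters' processing notes name affy and RMA, without versions. RMA corrects background, normalizes quantiles across arrays and summarises the probes of a set by median polish. This makes the arrays' distributions nearly equal, so that a change shared by most transcripts cannot be seen, and small differences of dim probe sets are compressed. The probe definition, the options and any filter on probe sets are not given in the sources used here, and no scanner files were analysed here. The deposited log2 values ran from 2.60 to 14.3, and the array medians from 6.85 to 6.94.

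The table held 16755 probe sets, of which 10 control probe sets were left out of the tests, leaving 16745. Probe sets were named through GEO's platform annotation, which can be old. Of these, 15445 had 1 gene symbol, 279 had several and were not named, and 1021 had none. The entrez identifiers of 15334 annotated probe sets were found in a RefSeq gene table, used for names only. The suffixes .L and .S mark the homeologous copies of a gene in this allotetraploid species, which were kept as separate genes. Probes of one homeolog can also bind transcripts of the other. A gene was represented by the probe set with the highest mean over the 4 arrays, which gave 11295 genes, 2683 of them with more than 1 probe set.

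Groups and replicate numbers were taken from the sample titles. The 2 SP600125 arrays were compared with the 2 controls with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a constant prior variance, 2 residual degrees of freedom, 2.10 prior degrees of freedom, two-sided) and Benjamini-Hochberg adjustment over all probe sets, at an adjusted p under 0.05. The unadjusted counts come from the same fit. The test was chosen to fit normalized log2 values. Gene lists were tested with camera on the same fit with 1 probe set per gene, an inter-gene correlation preset at 0.01, at least 5 measured members and Benjamini-Hochberg adjustment over the 24 lists. The calls were repeated with a correlation estimated from the residuals, and with fry, which tests whether the genes of a list move one way on balance and does not set them against other genes. With 2 residual degrees of freedom an estimated correlation is itself imprecise. The test then also refers to those degrees of freedom, so even a large shift may not be called. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

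The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. Of the 24 lists, 10 mark cell types: multiciliated cell regulators, motile cilia, ionocytes, small secretory and goblet cells, epidermal keratins and outer layer, basal layer and basement membrane, muscle and somites, neural and neural crest, endoderm with notochord, blood and kidney, and cement and hatching glands. The other 14 hold pathway or complex genes: JNK and AP-1, aryl hydrocarbon receptor, p53, unfolded protein and stress, NRF2, cell cycle, Notch, canonical Wnt, planar cell polarity, BMP and TGF-beta, actin, wound and inflammation, ribosomal proteins and the mitochondrial respiratory chain. Some genes stand in more than 1 list, for example 11 of 29 basal layer genes and 2 of 59 muscle genes. The rule named, for each direction, up to 12 genes with the largest change among those past the threshold, filled up with the smallest unadjusted p where fewer passed. It also named from each list up to 4 members that passed, or the 2 with the smallest p, and always mapk8, mapk9, mapk10, jun and cyp1 genes. The member with the brightest probe set in each of the 3 inner tissue lists was named in addition, after its values were seen. Brightness is not comparable between probe sets, so it does not rank transcripts by abundance.

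The alternatives were the replicate number as a block, probe sets with a mean log2 value under 5 left out, cyclic loess or quantile normalization applied again, a prior variance with trend and robust fitting, a minimum of 1.5-fold, an adjusted p under 0.1, 1 probe set per gene or the mean over a gene's probe sets, array weights, an estimated correlation, fry, and each array left out in turn. A run with an array left out has 1 residual degree of freedom and assumes that the lone array varies like the other group. It also leaves the replicate numbers unequal between the groups, so part of any difference by number enters the comparison.

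The scripts were tested on simulated data for the same comparison, 20 times, with 200 of 16745 probe sets changed. When the simulated arrays differed by replicate number as the real ones do, the fit recovered 0% of changes of 1, 2 or 3 log2 units at an adjusted p under 0.05, although 99.1% to 99.9% had the right sign. Without such differences it recovered 1.04%, 65.6% and 87.4%. A list of genes lowered by 0.5 log2 units was called in 20 of 20 simulations over 11295 genes, with 0% of the other lists called. The simulated noise was independent between genes, so the 0% does not measure false calls among correlated genes. On the real arrays, camera with the preset correlation called 13 of 24 lists in a split that matches no label.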

Results

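Gene expression was measured on Affymetrix arrays in whole skins isolated from Xenopus laevis embryos at stage 24. The 4 arrays comprised 2 control samples and 2 samples from embryos treated with SP600125, an ATP-competitive inhibitor of the c-Jun N-terminal kinases (JNK), from stage 14 to stage 24. The dose is labelled as 100 mM, a unit that the data could not check, and the controls are labelled as untreated with no vehicle named. Each sample pooled 20 skins. The labels do not say whether the samples of a group came from separate clutches, so p-values here measure the spread between these samples, which may be technical. The number of arrays limits the precision of every value. The series title gives depleted JNK signalling as the condition, but no measure of JNK activity was analysed here, so the comparison is of skins from SP600125-treated embryos with control skins.

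Skins from SP600125-treated embryos had lower levels of muscle and somite transcripts and higher levels of p53, DNA damage and apoptosis genes. The median log2 difference, SP600125 minus control, was −0.48 over 59 muscle and somite genes and 0.34 over 36 genes of the p53 list. Endoderm, notochord, blood and kidney genes, Notch pathway genes and canonical Wnt genes also lay lower, with medians of −0.25, −0.31 and −0.20. Motile cilia genes and ionocyte genes lay higher, with medians of 0.23 and 0.24. These shifts were called by camera with a preset inter-gene correlation, and 0 of 24 lists were called with an estimated correlation, where the lowest adjusted p was 0.292. With the preset correlation, camera called 14 lists for treatment and 13 in a split of the arrays that matches no label. Such a call is therefore weak evidence by itself.

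No single probe set passed the test. With limma and Benjamini-Hochberg adjustment over 16745 probe sets, 0 were higher and 0 lower at an adjusted p under 0.05, and the smallest adjusted p was 1. Among 16745 unchanged probe sets on arrays free of structure, chance would give 837 at an unadjusted p under 0.05. This fit counts the difference by replicate number as error, so 837 is no fair mark for its count. At that threshold 117 probe sets were higher and 152 lower, 269 in all. This total was 149 without control replicate 1, 430 without control replicate 2 and 516 without SP600125 replicate 1, and it was 158 when dim probe sets were left out. Both SP600125 arrays lay on one side of both controls for 1996 probe sets above and 1549 below, 21.2% of those tested. Chance gives 33.3% for exchangeable arrays, but replicate number took up 62.7% of the sum of squares and treatment 20.8%, so the 2 shares are not directly comparable. Of the probe sets on one side, 83 were at least 2-fold higher and 107 at least 2-fold lower.

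None of the single genes below passed, so their values are given as RMA log2 levels (mean ± SD of 2 arrays per group) or as log2 differences ± SE of the limma fit, with an adjusted p of 1 for each. Some of the genes named below were dim, with a mean log2 value under 5: g6pc1.1.L, krt17.S, pax7.L, lyz.L, rpl29.S, en2.L, en2.S, cyp1a1.L, cyp1a1.S and mapk8.S. The 12 genes with higher means and the smallest p included enzymes of glucose metabolism. The level of pck1.S, the cytosolic phosphoenolpyruvate carboxykinase of gluconeogenesis, was 4.38 ± 1.28 in controls and 8.22 ± 1.00 after SP600125. The glucose-6-phosphatase genes g6pc1.3.L and g6pc1.1.L differed by 3.79 ± 0.83 and 1.47 ± 0.22, while g6pc1.1.S, g6pc1.2.L and g6pc1.2.S differed by −0.03, 0.21 and 0.02. Those 3 were dim in all arrays, and g6pc1.1.L was as dim in the controls, at 3.65 ± 0.13. The difference of pdk4.S, a kinase that inhibits pyruvate dehydrogenase, was 1.86 ± 0.41. The cytochrome P450 gene cyp2j2.L read 5.02 ± 0.72 in controls and 8.31 ± 0.51 after treatment. Its other probe set differed by 3.03 ± 0.19. The remaining genes were gabarapl1.S (1.45 ± 0.20), an autophagy gene, abcg2.L (1.59 ± 0.25), an efflux transporter, and higd1a.S (9.59 ± 0.02 in controls, 10.79 ± 0.17 after SP600125), a mitochondrial protein induced by hypoxia. They also included ap4m1.S (1.21 ± 0.20), nupr1.L (1.21 ± 0.27), a stress-induced nuclear protein, glul-like.1.S (1.23 ± 0.28) and dapl1.L (1.09 ± 0.24). The other 4 probe sets of abcg2.L ranged from −0.11 to 0.88, and the other probe set of ap4m1.S differed by 0.38 ± 0.27. Those of dapl1.L differed by 0.25 ± 0.22 and 1.58 ± 0.37.

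Of the 12 genes with lower means, 4 stand in the muscle and somite list and 2 in the endoderm list. The largest difference of these was in darmin.L, a peptidase gene of the embryonic gut endoderm, at 8.29 ± 0.66 in controls and 4.95 ± 0.82 after SP600125. The endodermal and cardiac transcription factor gata4.L differed by −1.41 ± 0.20. The muscle and somite genes were the myosin heavy chain myh8.L (−2.65 ± 0.45), the muscle methyltransferase smyd1.L (−1.62 ± 0.29), and the transcription factors myf5.L (−1.36 ± 0.24) and pax3.S (−1.01 ± 0.19). The muscle calcium channel subunit cacng1.L, in none of the 24 lists, differed by −1.85 ± 0.29. The segmentation gene hes7.2.L, a transcriptional repressor under Notch control, differed by −1.18 ± 0.20. The others were thbs4.S (−1.59 ± 0.26), a matrix protein of tendon and muscle, hao1.L (−1.09 ± 0.21), a peroxisomal oxidase, ppp1r3b.L (−1.09 ± 0.21), a glycogen-targeting phosphatase subunit, and ftsj1.S (−1.04 ± 0.19), a tRNA methyltransferase. Further probe sets differed less for darmin.L (−0.56 ± 0.28), gata4.L (−0.01 ± 0.26) and myh8.L (−0.73 ± 0.38 and −1.54 ± 0.67).

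**Figure D1:**
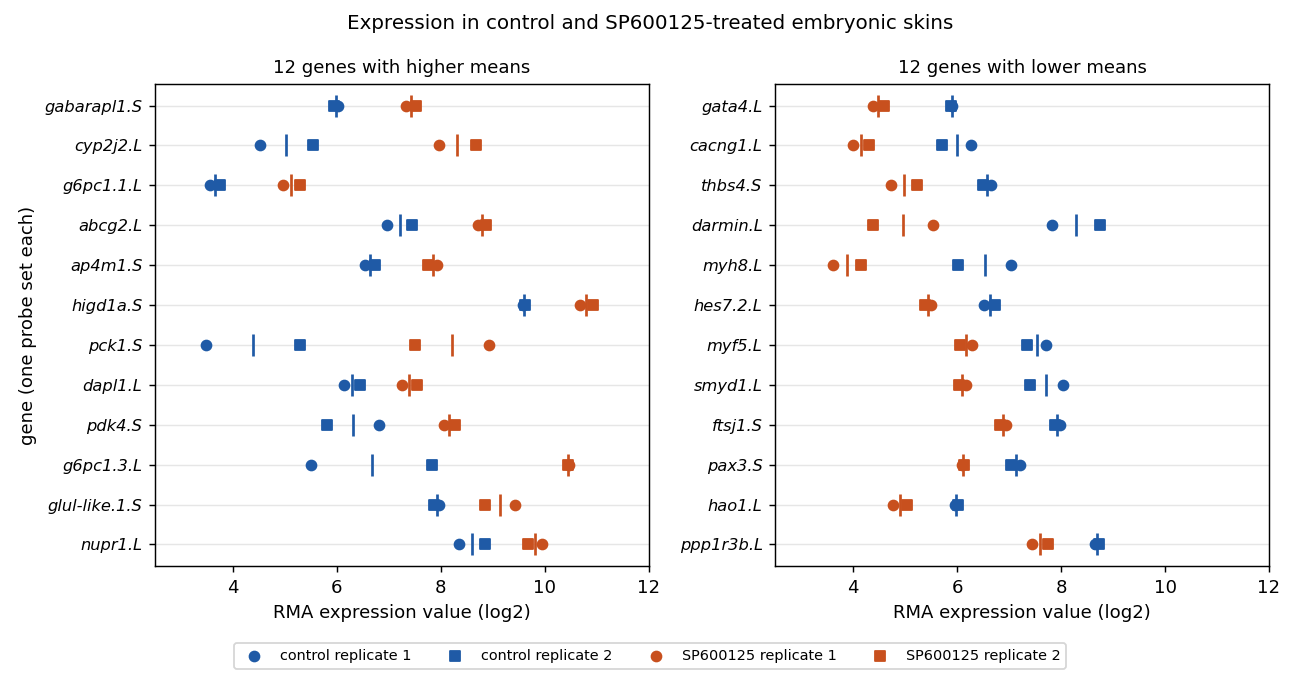
RMA expression values (x axis, log2) of the 12 genes with higher and the 12 with lower means after SP600125 and the smallest p (y axis), with 1 point per array (blue, control; orange, SP600125; circle, replicate 1; square, replicate 2) and a vertical bar at each group's mean. In every gene shown both SP600125 arrays lie on one side of both controls, and the controls of g6pc1.3.L and pck1.S stand furthest apart, with SDs of 1.64 and 1.28.

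Muscle and somite genes, which mark tissue under the skin, were lower as a list (camera adjusted p = 1.4e-19, and adjusted p = 0.406 with an estimated correlation). Of 59 measured members 50 had lower means, and in 26 both SP600125 arrays lay below both controls. The member with the brightest probe set, the cardiac and skeletal actin actc1.L, read 11.10 ± 0.94 in controls and 9.13 ± 0.28 after SP600125 (SD, n = 2). The 61 endoderm, notochord, blood and kidney genes were lower too (camera adjusted p = 7.7e-09, and adjusted p = 0.292 with an estimated correlation), with 49 lower means. The brightest probe set of that list, for a2m.S, differed by −0.84 ± 0.24. The medians of both lists were below 0 in all 4 pairings of a treated with a control array, and both calls held with each array left out in turn. The endoderm list's median was −0.14 without control replicate 1, and with dim probe sets left out the medians were −1.26 for muscle and −0.58 for endoderm.

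Neural and neural crest genes, the remaining list of inner tissue, did not move in the same way in every array. The list was called lower (median −0.20 over 75 genes, camera adjusted p = 0.000168, and adjusted p = 0.690 with an estimated correlation), with en2.L at −1.10 ± 0.29 and en2.S at −0.86 ± 0.25, both encoding a midbrain transcription factor. Without control replicate 1 it was called higher (adjusted p = 0.0282, median 0.06), and without control replicate 2 the median was −0.54. Its brightest probe set, for syt1.L, differed by 0.05 ± 0.19.

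Notch pathway genes were lower as a list (camera adjusted p = 1.4e-05, and adjusted p = 0.444 with an estimated correlation), with 23 of 30 means lower. The Notch targets esr-5.L and hes5.1.L differed by −1.44 ± 0.41 and −1.09 ± 0.35. The call was lost without control replicate 1 (adjusted p = 0.402, median −0.07), and the median was −0.67 without control replicate 2 and −0.16 without SP600125 replicate 2. Canonical Wnt genes were lower (camera adjusted p = 1.3e-05, and adjusted p = 0.406 with an estimated correlation), with 36 of 47 means lower. The smallest p among them belonged to msgn1.S (−1.12 ± 0.27) and msgn1.L (−1.60 ± 0.39), which encode a transcription factor of presomitic mesoderm. This call held with each array left out, with medians of −0.10 without control replicate 1 and −0.11 without SP600125 replicate 1. Planar cell polarity and non-canonical Wnt genes were lower (median −0.22, 26 of 32 means lower, camera adjusted p = 0.000223, and adjusted p = 0.444 with an estimated correlation), with wnt5b.S at −0.69 ± 0.20 and the Wnt receptor ror2.L at −0.58 ± 0.26. That call was lost without control replicate 1 (median −0.02) and without SP600125 replicate 2 (median −0.03). The median was −0.61 without control replicate 2 and −0.40 without SP600125 replicate 1. Within replicate numbers 1 and 2 the medians were −0.24 and −0.07. For number 2 minus number 1 the median was −0.49, and part of that difference enters each run with an array left out. The Notch, Wnt and polarity shifts stood beside the lower muscle list, with its median of −0.48. Of the genes named here, esr-5.L, hes5.1.L, msgn1.S and msgn1.L also stand in a list of presomitic mesoderm genes given below. Whether the Notch and Wnt shifts are separate from lower mesoderm transcripts was not tested.

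Motile cilia structural genes, expressed in the multiciliated cells of the skin, were higher as a list (camera adjusted p = 0.000162, and adjusted p = 0.444 with an estimated correlation), with 52 of 69 means higher. Examples were lrrc34.L (0.42 ± 0.19) and odf2l.L (0.56 ± 0.26). Without SP600125 replicate 1 the call was lost (adjusted p = 0.0746), and without control replicate 1 the median was 0.07. The list of multiciliated cell regulators gave no call (median 0.02 over 29 genes, camera adjusted p = 0.985). It also holds centriole genes, so it does not measure regulators of cell fate alone. Its members with the smallest p were ccdc78.S (−0.73 ± 0.47) and cep63.L (−0.37 ± 0.27). Ionocyte genes were higher (camera adjusted p = 0.000192, and adjusted p = 0.444 with an estimated correlation), with 27 of 37 means higher. The ionocyte transcription factor foxi1.L differed by 0.61 ± 0.20 and the proton pump subunit atp6v1f.L by 0.69 ± 0.23. That call was lost without SP600125 replicate 1 (adjusted p = 0.796, median 0.12), and the median was 0.16 without control replicate 1. Both lists had medians above 0 in all 4 pairings of arrays. Their shifts stood beside the lower muscle and endoderm lists, with medians of −0.48 and −0.25.

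Epidermal keratins and outer layer genes were called higher by a small amount (median 0.11, 36 of 48 means higher, camera adjusted p = 0.0357, and adjusted p = 0.601 with an estimated correlation), with krt17.S at 0.38 ± 0.23 and anxa2.L at 0.34 ± 0.21. The call was lost without control replicate 1 (adjusted p = 0.349, median 0.05), control replicate 2 (adjusted p = 0.0783) or SP600125 replicate 1 (adjusted p = 0.638), after renewed quantile normalization (adjusted p = 0.0772) and with dim probe sets left out (adjusted p = 0.0852). Genes of the basal layer and basement membrane were called lower (median −0.17, 21 of 29 means lower, camera adjusted p = 0.00312, and adjusted p = 0.699 with an estimated correlation). The integrin itgb1.L differed by −0.58 ± 0.21 and the nidogen nid2.L by −0.62 ± 0.27. The direction turned without control replicate 1 (median 0.04) and without SP600125 replicate 2 (median 0.15). The median was −0.42 without control replicate 2 and −0.57 without SP600125 replicate 1. Within replicate numbers 1 and 2 the medians were −0.15 and −0.30, both lower. The median for number 2 minus number 1 was −0.77, and part of that difference enters each run with an array left out. In the list of small secretory and goblet cell genes, pax7.L differed by −0.46 ± 0.27 and upk3a.L by 0.18 ± 0.19. Whether pax7.L marks these cells was not tested. The list gave no call (median −0.03 over 24 genes, camera adjusted p = 0.829). The cement and hatching gland genes gave none either (median −0.12 over 7 genes, adjusted p = 0.361), with pitx1.L at −0.81 ± 0.80 and dkk1.S at 0.45 ± 0.46, but were called lower without SP600125 replicate 2 (adjusted p = 0.0301), and turned without control replicate 1 (adjusted p = 0.894) or SP600125 replicate 1 (adjusted p = 0.667).

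The p53, DNA damage and apoptosis genes were higher as a list (camera adjusted p = 5.0e-07, and adjusted p = 0.292 with an estimated correlation), with 31 of 36 means higher. The initiator caspase genes casp10.L and casp10.S differed by 1.05 ± 0.24 and 0.72 ± 0.21. The call held with each array left out, and the median was above 0 in all 4 pairings of arrays. NRF2 and oxidative stress genes were called higher (median 0.20, 30 of 41 means higher, camera adjusted p = 0.00737, and adjusted p = 0.775 with an estimated correlation). The direction turned without control replicate 1 (adjusted p = 0.104), and the call was lost without SP600125 replicate 1 (adjusted p = 0.261). The median was 0.57 without control replicate 2. Aryl hydrocarbon receptor targets were called higher (median 0.10, 10 of 14 means higher, camera adjusted p = 0.0280, and adjusted p = 0.444 with an estimated correlation). Both lists hold the transferase gene gsta1.S (0.57 ± 0.22) and nfe2l2.S (0.95 ± 0.36), the latter encoding NRF2 itself. Of the receptor's best-known target, cyp1a1.L, at 4.05 ± 0.22 in controls, differed by 1.75 ± 0.68, and cyp1a1.S differed by 0.25 ± 0.19. The receptor call was lost without control replicate 2 (adjusted p = 0.287), without SP600125 replicate 1 (adjusted p = 0.200) and with dim probe sets left out (adjusted p = 0.123). The median lay between 0.15 and 0.23 in the 4 runs with an array left out and at 0.27 without dim probe sets. Mitochondrial respiratory chain genes were called higher (median 0.15, 49 of 63 means higher, camera adjusted p = 0.0155, and adjusted p = 0.812 with an estimated correlation), with ndufb3.S at 0.45 ± 0.22 and ndufa6.S at 0.44 ± 0.23. That direction turned without control replicate 1 (adjusted p = 0.349), and the call was lost without SP600125 replicate 1 (adjusted p = 0.251) or 2 (adjusted p = 0.0862), with a median of 0.33 without control replicate 2.

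JNK pathway and AP-1 genes showed no shift that passed (median 0.06, 24 of 42 means higher, camera adjusted p = 0.829). The kinase gene mapk8.L, which encodes JNK1, differed by −0.20 ± 0.19 and mapk8.S by 0.08 ± 0.30. The AP-1 subunit gene jun.L read 5.81 ± 0.04 in controls and 5.74 ± 0.13 after SP600125, and the growth arrest genes gadd45g.L and gadd45g.S differed by 0.62 ± 0.33 and 0.44 ± 0.24. The sign of jun.L and mapk8.S changed with single arrays left out, to 0.02 for jun.L without SP600125 replicate 2 and to −0.19 for mapk8.S without control replicate 1. The list was called higher without SP600125 replicate 2 (adjusted p = 0.0398, median 0.12), and its direction turned without SP600125 replicate 1 (adjusted p = 0.261, median −0.08). A level of transcript says nothing about kinase activity, and mapk9 and mapk10 were not matched by symbol to a probe set.

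The other pathway lists were not called. BMP and TGF-beta genes had a median of −0.06 over 59 genes (camera adjusted p = 0.0696), with the ligand tgfb1.L at −0.98 ± 0.21 and tgif1.S at −0.44 ± 0.23, and were called lower without control replicate 2 (adjusted p = 0.00267), with the direction turned without control replicate 1 (adjusted p = 0.654). Cell cycle genes had a median of 0.09 over 114 genes (adjusted p = 0.186), with ube2c.S at 0.60 ± 0.20 and the cyclin ccnd1.S at −0.59 ± 0.23, and were called higher without control replicate 1 (adjusted p = 0.00964) or SP600125 replicate 1 (adjusted p = 0.0374). Their direction turned without control replicate 2 (adjusted p = 0.744) or SP600125 replicate 2 (adjusted p = 0.684, median −0.03). Actin cytoskeleton genes had a median of −0.02 over 73 genes (adjusted p = 0.177), with the kinase src.L at −0.46 ± 0.22, and were called lower without control replicate 2 (adjusted p = 0.0487) or SP600125 replicate 1 (adjusted p = 0.00165). Their direction turned without control replicate 1 (adjusted p = 0.946) or SP600125 replicate 2 (adjusted p = 0.0834, median 0.10). Unfolded protein, integrated stress and heat shock genes had a median of −0.09 over 58 genes (adjusted p = 0.205), with ddit4.S at 0.63 ± 0.20. Wound, inflammation and matrix protease genes had a median of 0.02 over 51 genes (adjusted p = 0.977), with mmp15.L at −0.56 ± 0.19 and lyz.L at 0.41 ± 0.19. Ribosomal protein genes had a median of 0.01 over 86 genes (adjusted p = 0.985), with rps6.L at 0.67 ± 0.24 and rpl29.S at −0.29 ± 0.22. In the wound, ribosomal and multiciliated regulator lists the median and mean were above 0 while camera, which sets a list against all other genes, gave a lower direction. Cyclic loess moved the wound and ribosomal medians below 0, to −0.02 and −0.01.

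**Figure D2:**
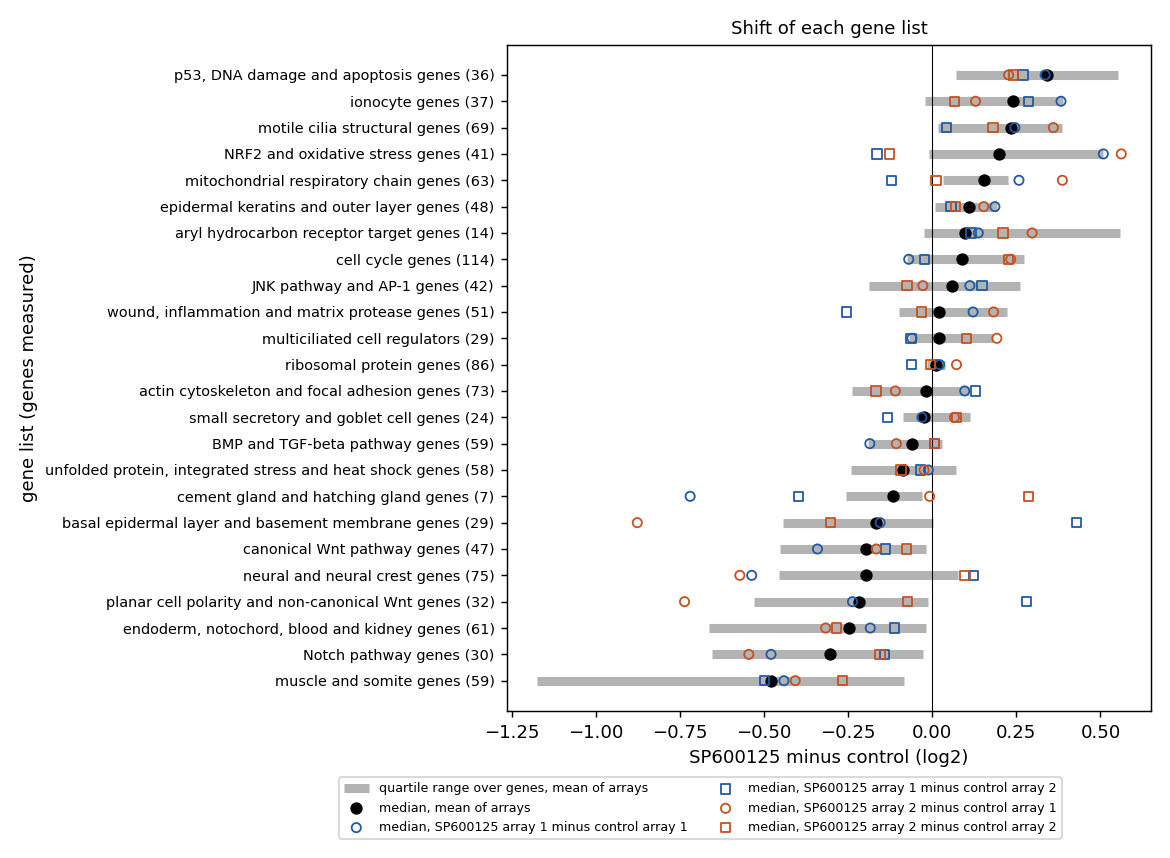
Log2 difference, SP600125 minus control (x axis), of the 24 gene lists (y axis, genes measured in brackets), with the median of the group means as a black point, its quartile range over genes as a grey bar, and open symbols for the medians of the 4 pairings of a treated with a control array. The muscle list lies lowest at −0.48, the p53 list highest at 0.34, and the neural list has pairings on both sides of 0.

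Across the 24 lists, limma with Benjamini-Hochberg adjustment over all genes passed 0 members of any list, and adjusted over the list alone also 0, with a lowest adjusted p of 0.0897 in the muscle list, where 15 members were lower at an unadjusted p under 0.05. Camera called 14 lists, 7 higher and 7 lower, of which 4 held direction and call with each array left out (muscle, endoderm, p53 and canonical Wnt), while fry called 0, with a lowest adjusted p of 0.187. At an unadjusted p under 0.05, 3 lists passed with fry and 2 with an estimated correlation.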

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

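The explanations in this part were weighed with tests chosen after the results were seen, and the test of single probe sets was also split by gene and narrowed after its values were seen.

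The 3 control probe sets for gapdh, a glycolytic enzyme, stand outside the tested probe sets and read higher in the SP600125 arrays. The 3' probe set read 9.01 ± 0.60 in controls and 10.30 ± 0.53 after SP600125 (log2, SD, n = 2), a difference of 1.295. The 5' and middle probe sets differed by 1.55 and 1.37. In each of the 3, both SP600125 arrays lay above both controls. The 3' actin control probe set differed by −0.01.

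Of 12 tested probe sets of pck1, g6pc1, pdk4 and gapdh, 9 read higher in both SP600125 arrays than in both controls. Among the probe sets of pck1, pdk4 and gapdh not named for a small p, 5 of 5 did so. Without gapdh, a gene already seen higher on its control probe sets, 3 of 3 did so. Only 1 of them is a further probe set of a named gene, pdk4.S, where its difference of 1.41 argues against an artifact of single probe sets. The others, of pck1.L, pdk4.L, gapdh.L and gapdh.S, are weaker evidence. Homeologs were kept as separate genes, and probes of one can bind transcripts of the other. The margin of gapdh.S was small, 11.71 in SP600125 replicate 2 against 11.68 in control replicate 2. Such an artifact thus stays open for pck1 and gapdh. It also stays open for g6pc1, where 0 of 3 did so and g6pc1.1.S (−0.03), g6pc1.2.L (0.21) and g6pc1.2.S (0.02) were dim in all arrays. Fewer cells of other tissues would raise epidermal genes to a like degree, if these genes are read from the whole epidermis, which was not tested. The upper quartile of the epidermal list was 0.193, below the smallest of those 9 differences, 0.89. Its brightest members, such as krt70.S at 14.12 ± 0.03 in controls, stood near the arrays' highest values, with little room to rise. The comparison thus goes against a like rise and does not exclude a change of composition. For a shift of FoxO target and fasting response genes, a list of 44 genes written after the pattern was seen gave, by camera with an estimated correlation, an unadjusted p of 0.0392 and an adjusted p of 0.0783 over 4 such lists (adjusted p = 5.67e-15 with the preset correlation), and its 10 members not looked at beforehand, a restriction made after those values were seen, were all higher (median 0.34), with an unadjusted p of 0.153, or 9.9994e-04 with the preset correlation. The whole list holds pck1, g6pc1, pdk4 and gabarapl1 themselves, so its value restates the pattern and tests nothing, and such a shift stays open, as does a difference in handling between the samples.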

How the results depend on the processing

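All alternatives in this part were planned, except the replicate block with an estimated correlation, which was chosen after seeing the data. With limma, 0 probe sets passed at an adjusted p under 0.05 in any alternative, and 0 under 0.1, where 117 were higher and 152 lower at an unadjusted p under 0.05. Those unadjusted counts were 62 and 96 with dim probe sets left out, which tests fewer probe sets, and ranged from 57 to 215 and from 92 to 301 with an array left out. The other alternatives without a block stayed within 1.5 times. Dim signal limits the lists of muscle and of small secretory cells most, with 31 of 59 and 14 of 24 members under a mean of 5. Of 69 named genes 3 changed sign with an array left out: jun.L from −0.16 to 0.023, mapk8.S from −0.19 to 0.36 and pitx1.L from −1.82 to 0.20. Where a call or direction changed and no cause is given, the cause was not tested.

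The replicate numbers do not pair the samples by any label, and deviations of same-numbered arrays correlated at 0.585. With the replicate number as a block (replicate block), 453 probe sets were higher and 610 lower at an unadjusted p under 0.05, and 0 passed adjustment (smallest adjusted p 0.761). In simulations whose replicate differences were paired by construction, the block recovered 0.0746%, 11.5% and 54.1% of changes of 1, 2 and 3 log2 units at an adjusted p under 0.05, against 0% without it. The block ended the call of the aryl hydrocarbon receptor targets (adjusted p = 0.0534) and changed no other call. It turned the direction of multiciliated regulators (adjusted p = 0.935), ribosomal genes (adjusted p = 0.938) and wound genes (adjusted p = 0.652). The block with an estimated correlation left 1 residual degree of freedom, on which that test draws, so almost no shift could be called. No list was called: the adjusted p was 0.665 for muscle, endoderm, p53, Notch, Wnt, polarity, motile cilia and basal layer genes. It was 0.699 for receptor targets and 0.837 for NRF2, keratin, ionocyte and neural genes and, turned in direction, wound genes. It was 0.863 for respiratory chain genes and 0.978 for multiciliated regulators and ribosomal genes, both turned.

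With an estimated correlation 0 of the 14 calls held. For the endoderm list the unadjusted camera p was 0.0160, against 6.4e-10 with the preset correlation, so a lack of calls here says little about the shifts. That test also refers to the 2 residual degrees of freedom in place of a normal distribution, and the estimates for the endoderm, p53 and receptor target lists, −0.0158, −0.0277 and −0.0606, lay below the preset 0.01, so a higher correlation did not end those calls. In all other called lists the estimate lay above the preset, from 0.032 for Wnt to 0.504 for respiratory chain genes. It was 0.147 for muscle, 0.152 for Notch, 0.282 for neural, 0.392 for NRF2 and 0.402 for basal layer genes. For these lists the p-values with the preset correlation assume less correlation than was estimated. The adjusted p was 0.292 for endoderm and p53 genes, 0.406 for muscle and Wnt genes, and 0.444 for Notch, receptor target, ionocyte, motile cilia and polarity genes. It was 0.601 for keratin, 0.690 for neural, 0.699 for basal layer, 0.775 for NRF2 and 0.812 for respiratory chain genes. With fry, which does not set a list against other genes, 0 were called. Its adjusted p was 0.187 for p53 genes, 0.390 for muscle and endoderm genes, 0.542 for receptor targets, and 0.683 for Wnt, keratin, ionocyte and motile cilia genes. It was 0.908 for NRF2, Notch, basal layer, respiratory chain, neural and polarity genes and, turned, for multiciliated regulators and ribosomal genes. Wound genes (adjusted p = 0.944) and small secretory genes (adjusted p = 0.995) turned as well.

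Leaving out dim probe sets ended the calls of receptor targets (adjusted p = 0.123) and keratins (adjusted p = 0.0852), and turned ribosomal (adjusted p = 0.943) and small secretory genes (adjusted p = 0.674). Renewed quantile normalization ended the keratin call (adjusted p = 0.0772). Cyclic loess and the mean over probe sets ended none.

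With each array left out in turn, the lowest and highest adjusted p were as follows. Among called lists that kept their direction they were 0.00109 and 0.0746 for motile cilia, 1.2e-07 and 0.796 for ionocyte, and 0.0301 and 0.638 for keratin genes. They were 1.7e-08 and 0.402 for Notch, 8.4e-07 and 0.894 for polarity, and 0.0184 and 0.287 for receptor target genes. Among called lists that turned in a run they were 8.7e-07 and 0.946 for basal layer, 9.9e-15 and 0.0282 for neural, 6.9e-09 and 0.261 for NRF2, and 1.9e-05 and 0.349 for respiratory chain genes. All 10 lists without a call turned in at least 1 run. Among them the values were 0.00267 and 0.654 for BMP, 0.00165 and 0.946 for actin, 0.00964 and 0.744 for cell cycle, and 0.0301 and 0.894 for gland genes. They were 0.0398 and 0.819 for JNK, 0.684 and 0.819 for multiciliated regulator, and 0.738 and 0.807 for ribosomal genes. They were 0.256 and 0.946 for small secretory, 0.143 and 0.757 for unfolded protein, and 0.0547 and 0.516 for wound genes.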

Other observations

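The gene lists of the next paragraph and all tests of explanations in this part were chosen after the results were seen, and the rule that a normalization which moves little decides nothing was set after its movement was seen.

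Genes of the presomitic mesoderm and early muscle lineage were lower after SP600125 in 25 of 27 measured members (median −0.89, and −1.11 and −0.47 within replicate numbers 1 and 2), with an adjusted p over 4 such lists of 0.0783 by camera with an estimated correlation and 1.91e-19 with the preset one. Among 34 genes of differentiated muscle 31 were lower (median −1.26, and −2.08 and −0.62 within the numbers, adjusted p = 0.0856 and 1.24e-25), and in 22 both SP600125 arrays lay below both controls. Both lists share members with the muscle list fixed beforehand, and each holds 3 genes named for a small p, such as cacng1.L and hes7.2.L. Their counts and p thus partly restate the pattern and are not independent evidence of its direction. The presomitic list also shares members with the Notch, Wnt and polarity lists, such as esr-5.L, msgn1.L and pcdh8.L. The 25 glycolysis genes had a median of 0.06 (adjusted p = 0.275 and 0.0272). None of these lists passed with an estimated correlation, and all did with the preset one.

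The lower muscle and inner tissue lists were set against technical explanations. A scaling offset common to all probe sets could not by itself lower muscle genes and raise p53 genes. Quartile ranges were −1.18 to −0.08 for muscle and 0.07 to 0.55 for p53 genes. The median difference over all probe sets was 0.01, but RMA makes the arrays' distributions nearly equal, so that value tests nothing. Scaling that depends on brightness stays open: the muscle median was −0.53 under cyclic loess against −0.48 as deposited. The deposited values were already normalized by RMA, though, and loess moved the probe sets by a median of only 0.02, which decides nothing. Less inner tissue carried along with the treated skins may lower such genes: within replicate number 1 the medians of muscle, neural and endoderm genes were −0.44, −0.54 and −0.18, and within number 2 they were −0.27, 0.10 and −0.28, where the neural value, 0.0974, has a quartile range from −0.22 to 0.35, and among members with a mean of at least 5 the quartile ranges there were −0.23 to 0.41 for neural and −1.24 to −0.27 for muscle genes, which do not overlap. The neural median was also above 0, at 0.12, for SP600125 replicate 1 minus control replicate 2, where the muscle median was −0.50. Against control replicate 1 it was −0.54 and −0.57, so its sign followed the control array used. An equal loss of all inner tissue thus goes against the bright genes of 1 pair of arrays and the neural medians against 1 control array, too few to exclude it. A loss of muscle by the treatment itself and a difference in dissection cannot be told apart here. Only 3 splits of the 4 arrays exist, too few for a share under 0.05: of 24 lists, camera called 14 in the real split, the only 1 of the 3 with as many, and 13 in the highest other. That other split, which matches no label, also called the muscle list (camera adjusted p = 0.0106, median 0.10).

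The arrays differed more by replicate number than by treatment. Replicate number took up 62.7% of the sum of squares, treatment 20.8% and the remainder 16.5%, and splitting the arrays by number gave 4063 probe sets at an unadjusted p under 0.05 with limma, against 269 for treatment, which points to a structure of the samples. Sequence variants under single probe sets would leave probe sets of a gene that share no sequence unrelated. Across 1056 genes with 2 bright probe sets the replicate differences correlated at r = 0.663, with genes not being independent replicates. The pairs were not checked for shared sequence, where a variant could move both, so the correlation does not exclude such variants. Array scaling stays open, since cyclic loess moved the probe sets of these normalized values by a median of only 0.06 and left a share of 62.5%. Clutch, exact stage and dissection stay open, since the labels give none of them per sample, and of the 24 lists the basal layer list differed most by number, with a median of −0.77 for number 2 minus number 1.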
